A study of Mus musculus with 4 samples.

How the data were processed

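Single-cell RNA was measured in cells of the thoracic aorta and arch of male ApoE-deficient mice, which were fed chow and either drank water with imidazole propionate (ImP), a product of gut microbes, at 400 µg per mouse and day, or received none, for 4 or 8 weeks. Per the labels' protocols, the fat around the vessel was removed, the tissue was digested with a mixture of enzymes, live cells were sorted, and the cells of each pool were marked with a cholesterol-modified oligonucleotide tag before they were loaded together on a droplet device with 3' chemistry. Each pool held the cells of 3 mice, and these pools, not the cells, were the replicates. There were 8 pools in 4 groups (control or ImP, 4 or 8 weeks), with 2 pools per group. The pools came in 2 multiplexed runs of 4 pools each, and each run held 1 pool of every group, so that the number of a pool (1 or 2) is also the number of its run.

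The deposited matrices held UMI counts per gene and cell, and a second kind of deposited matrix held UMI counts per tag and barcode for each run. Per the submitters' processing notes, Cell Ranger 6.1.2, R 4.1.2, Seurat 4.2.1 and the builds mm10 and GRCm38.p6 were used, with no role given for each. The deposited counts were whole numbers whose totals differed between pools, so they had not been scaled. The filters that the authors applied to cells are not stated in the labels, but every deposited cell had at least 513 genes, at least 1001 UMIs, at most 5995 genes and at most 7.48% mitochondrial UMIs, so the deposited cells had been filtered before. The total of UMIs per pool ranged from 12242556 in ImP pool 1 of 4 weeks to 28901026 in control pool 2 of 4 weeks. The files named 22391 genes by symbol alone, of which 21966 matched a symbol of the GENCODE M21 annotation (GRCm38) and 425 did not. These 425 were kept under the symbol in the files. Positions are from that annotation.

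The tags were used only to check that each matrix belonged to the pool named in its label. The pool's own tag was the most abundant tag in 91.97% to 100% of its cells. Replicates differed by more than sampling noise (chi-square per degree of freedom 9.62 in the ImP group of 4 weeks, the lowest of the groups). The matrices of a group were therefore not copies of each other. Matrices of different groups were not compared in this way. Whether pools of a run deviated together was checked once on log2 CPM from which the group means had been removed. Across genes, the deviations of the pools of run 1 correlated between groups with r of 0.357 to 0.554 over 4183 genes in SMC, 0.121 to 0.411 over 4380 genes in fibroblasts and 0.112 to 0.272 over 4774 genes in macrophages. Genes are not independent replicates, and these correlations show only that the runs differed. The comparisons had been fixed without a term for the run, and each was repeated with the run as a replicate block.

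Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, which removed none. Scrublet (scanpy 1.11.5, expected doublet rate 0.05) called 150 of 11880 cells doublets (1.26%), and 11730 cells were used. Values were scaled to the cell's total and log transformed, 2000 variable genes were reduced to 30 principal components, and a graph of 15 neighbours was clustered with leidenalg 0.10.2. The resolution of 0.2 was chosen after the clusters had been seen, because higher values split the smooth muscle cells (SMC) into many parts. There were 10 clusters, and 8 of them were named by lists of marker genes, giving 7 classes: SMC, fibroblast (clusters 1 and 2), macrophage, B cell, T cell, endothelial cell (EC) and lymphatic EC. The unnamed clusters 5 and 7 were counted in the totals only. The class with the highest mean marker score was the same as the class by cluster in 98.55% of cells. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

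Counts were summed per pool and class for the 3 classes with at least 30 cells in each pool: SMC, fibroblast and macrophage. Gene levels in CPM and log2 fold changes were computed from these sums, and the authors' counts were not otherwise changed. Sums were tested with edgeR 4.0.16 (R 4.3.3, TMM scaling, genes kept by filterByExpr, quasi-likelihood F test, 4 groups sharing 1 estimate of the spread), with Benjamini-Hochberg adjustment per class and comparison at 0.05. A standard error (SE) of a log2 fold change is its size divided by the square root of F. There were 5 comparisons: ImP against control at 4 weeks, at 8 weeks and as the mean of both times, the difference between the responses at 8 and 4 weeks, and controls at 8 against 4 weeks. The sums held 5063428 to 18289890 UMIs per pool in SMC, 3807161 to 8697659 in fibroblasts and 342533 to 1995315 in macrophages. The spread between pools of a group (biological coefficient of variation) was 7.5%, 10.6% and 18.8% in these classes. With pools of 3 mice the spread between mice could not be measured.

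Shares of cells were tested with edgeR on numbers of cells for the 7 classes and clusters 5 and 7, and for the 7 classes and fibroblast clusters 1 and 2 with exact permutation tests (two-sided) over the 70 assignments of the 8 pools, whose lowest p is 0.0286. Permuting within week gives 36 assignments and a lowest p of 0.0556, and a single week a lowest p of 0.333, so the exact tests over both weeks only could pass 0.05. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 with adjustment over 77 tests (26 lists in SMC, 26 in fibroblasts, 25 in macrophages), and again with a correlation estimated for each list. The lists for T cell activation, cytotoxic and Th1 cells, Th17 and gamma delta cells, regulatory T cells and naive T cells had fewer members in these classes and were not tested. Log2 fold changes within runs and list levels per pool used log2(CPM + 1).

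The comparisons, tests, marker and gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named, per class and ImP comparison, the 3 largest rises and falls among genes with an adjusted p under 0.05, a mean of at least 20 CPM and no overlap between arms. Where none passed, it named the 2 genes with the smallest p. It also named 2 to 4 passing members per list, and Nisch, Apoe, Vcam1, Icam1, Ccl2, Col1a1 and Acta2 in all cases where they were tested. For controls it named 2 genes each way. Other called genes were named because the counts were small, and genes called only with the replicate block were named by the same rule on that fit. Both were chosen after their values had been seen. Some genes that the rule named were withheld for evaluation, and their values are not given.

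Alternatives were a replicate block, DESeq2 1.42.0 on the same sums, median of ratios size factors, no filter on low counts, kept doublet calls, class by marker score, equal numbers of cells per pool, and leaving out each pool in turn. A looser filter on cells (at least 200 genes and at most 20% mitochondrial UMIs) kept the same cells and gave no other value. Added after the data had been seen were cells with at least 5000 UMIs, totals without lymphocytes or without lymphocytes and macrophages, each fibroblast cluster alone, and fibroblasts without the cells that held SMC-specific transcripts. Those cells had over 10% of the SMC median for 20 SMC-specific genes outside the contractile list.

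The tests were run on simulated data in which 200 genes had been changed. For the mean of both times, a 2-fold change was found for 92.4% of changed genes among 12285 in SMC, 75.8% among 12310 in fibroblasts and 55.4% among 6523 in macrophages. At 4 weeks these were 83.3%, 63.6% and 10.8%. Some calls were of genes that had not been changed. For the mean of both times these false calls were 10 of 184 in SMC, 19 of 166 in fibroblasts and 15 of 121 in macrophages. At 4 weeks they were 14 of 164, 17 of 133 and 4 of 61. In each class, false calls were in both comparisons a larger share than the threshold for adjusted p values is meant to allow. A halved SMC share was found in 3 of 50 draws (6%). These draws gave all 9 classes and clusters, rare ones included, the same spread (dispersion 0.512). They therefore do not measure the power of the edgeR test for the SMC share. A list raised 1.3-fold was found by camera with an estimated correlation in SMC and fibroblasts (adjusted p 0.0027 and 0.00579 for the mean of both times) and not in macrophages (adjusted p 0.083). The simulated genes were drawn independently and without a difference between runs. The power of that test on lists whose genes vary together was thus not measured.

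The level of Apoe says nothing about the knockout, since a 3' tag can lie outside the part that was disrupted. Symbols are all the files give, so near-identical genes such as Hspa1a and Hspa1b cannot be separated with certainty.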

Results

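The aortic wall of ApoE-deficient mice, which have high blood cholesterol and develop atherosclerosis, was profiled cell by cell after 4 or 8 weeks with or without imidazole propionate (ImP). Each of the 4 groups had 2 pools of 3 mice. The 8 pools held 897 to 2091 cells and 12242556 to 28901026 UMIs each, with a median of 12181 to 15043.5 UMIs per cell. After removal of doublet calls, 11730 cells were sorted into classes. SMC formed the largest class with 5618 cells (47.89%), followed by fibroblasts with 4439 cells (37.84%) and macrophages with 809 cells (6.9%). B cells (230), ECs (161), T cells (108) and lymphatic ECs (52) were less frequent. The fibroblasts formed a pair of clusters. Cluster 1, with 2186 cells, was marked by Penk, C3, Ly6c1 and Cd248, and cluster 2, with 2253 cells, by Fmod, Smoc2 and Angptl7.

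The first question was whether ImP changed the make-up of the cell suspension. SMC were a smaller part and fibroblasts a larger part of the cells from ImP-treated mice than of those from controls. SMC made up 57.3% ± 1.79 (SD, n = 4 pools) of the cells of control pools and 37.4% ± 3.79 (SD, n = 4) of the cells of ImP pools, and the highest ImP pool, at 41.2%, was below the lowest control pool, at 55.3%. Fibroblasts made up 30.6% ± 4.80 (SD, n = 4) in controls and 47.3% ± 7.79 (SD, n = 4) with ImP. By the means of the arms the difference lay in cluster 1, with 12.2% ± 0.832 (SD, n = 4) in controls and 27.0% ± 6.61 (SD, n = 4) with ImP. Cluster 2 had 18.4% ± 4.22 and 20.3% ± 3.62 (SD, n = 4 each). In run 2 at 8 weeks, however, both clusters were higher with ImP (cluster 1 24.2% against 11.3%, cluster 2 25.4% against 12.1%).

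The SMC, fibroblast and cluster 1 shares each had an exact permutation p of 0.0286, the smallest that 70 assignments can give, and an adjusted p of 0.0857 over 9 shares. The edgeR test of shares covered the classes and the unnamed clusters 5 and 7, but not fibroblast clusters 1 and 2, and none passed over both times or at either time. The log2 fold change of the SMC share was −0.62 (SE 0.173, adjusted p 0.133, 0.247 with a replicate block) over both times, −0.65 at 4 weeks and −0.59 at 8 weeks. For fibroblasts it was 0.63 (SE 0.216, adjusted p 0.141, 0.247 with a replicate block). The SMC share was different by −23.12 percentage points in run 1 and −16.8 in run 2, and the cluster 1 share by 15.02 and 14.55. The cluster 2 share differed by −1.99 and 5.97. The response did not pass a test of difference between the times (SMC 0.06, adjusted p 0.939 by edgeR). ECs, which line the vessel, made up 0.932% ± 0.21 (SD, n = 4) in controls and 1.77% ± 0.762 (SD, n = 4) with ImP (exact permutation p 0.0857). Macrophages made up 7.62% ± 7.22 in controls and 5.97% ± 2.06 with ImP (SD, n = 4 each; exact permutation p 0.943). Shares of sorted cells depend on how well each cell type came out of the digested tissue, and they give no absolute numbers.

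**Figure D1:**
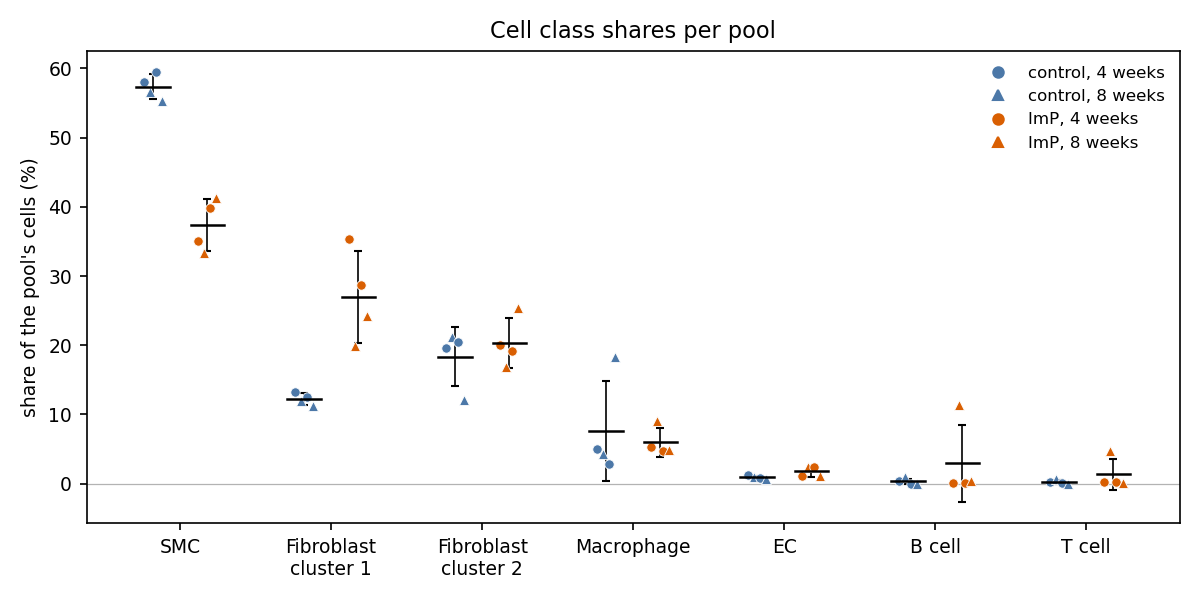
Share of the cells of each pool (%, vertical axis) in 7 classes or clusters, with control pools in blue, ImP pools in orange, circles for 4 weeks and triangles for 8 weeks. Black bars are means of 4 pools with SD; the 4 ImP pools lie below the 4 control pools for SMC and above them for fibroblast cluster 1.

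The second question was which genes ImP changed over both times, with 4 pools against 4. The fibroblasts, which make most of the collagen of the outer wall, gave most of the calls. In them 13 genes passed, 6 higher and 7 lower with ImP. The largest rise was in Dkk2, a secreted regulator of Wnt signalling (22.2 ± 13.1 CPM with ImP against 8.59 ± 5.54 in controls, SD, n = 4 each). It was followed by Ifit1, an interferon-induced antiviral gene (25.6 ± 2.59 against 11.5 ± 1.80 CPM), and Cilp, a matrix protein of cartilage and fibrous tissue (74.7 ± 14.7 against 36.0 ± 14.2 CPM). The largest fall was in Hspa1a, a heat-inducible chaperone (531 ± 117 against 917 ± 147 CPM).

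Over both times the log2 fold changes in fibroblasts by edgeR were 1.38 for Dkk2 (SE 0.156, adjusted p 0.0174), 1.16 for Ifit1 (SE 0.125, adjusted p 0.0170) and 1.13 for Cilp (SE 0.114, adjusted p 0.0170). Hyou1, a chaperone of the endoplasmic reticulum (ER), rose by 0.84 (adjusted p 0.0411), the cell adhesion molecule Cadm3 by 0.90 (adjusted p 0.0331) and the matrix gene Hmcn2 by 0.76 (adjusted p 0.0331). Hspa1a fell by 0.81 (SE 0.102, adjusted p 0.0273), Gucy1a1, a subunit of the nitric oxide receptor, by 0.74 (adjusted p 0.0273), Trp53inp1, a p53 target, by 0.71 (adjusted p 0.0405), and Ptch1, the hedgehog receptor, by 0.69 (adjusted p 0.0405). Without the fibroblasts that held SMC-specific transcripts, Gucy1a1 (−0.57, adjusted p 0.136) and Tm4sf1 (−0.65, adjusted p 0.0807) lost their call, the latter with nearly the same fold change. With doublet calls kept, Gucy1a1 (−0.54, adjusted p 0.0813), Art4 (−0.53, 0.0741), Trp53inp1 (−0.70, 0.0621) and Hyou1 (0.84, 0.0504) lost theirs, and only for Gucy1a1 did the fold change move by more than 0.02. Tm4sf1 fell by 0.70, Cd200, which restrains myeloid cells, by 0.65, and Art4 by 0.54 (adjusted p 0.0331, 0.0331 and 0.0499). The ImP and control pools differed in the same direction within each run for all 13 genes, as for Cilp (0.97 in run 1 and 1.23 in run 2 on log2 values) and Ifit1 (0.89 and 1.29). The genes had been picked by a test on these same pools, so this direction describes them and is no separate test. Dkk2 is at chromosome 3, 132085292 to 132180304, Ifit1 at chromosome 19, 34640871 to 34650009, Cilp at chromosome 9, 65265180 to 65280605, and Hspa1a at chromosome 17, 34969190 to 34972156 (GRCm38).

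With a replicate block 192 genes passed in fibroblasts (94 higher, 98 lower) and DESeq2 called 131, each with all 13 genes. Without a filter on low counts 716 passed, but each gene's spread was then taken wholly from the trend over genes (prior degrees of freedom infinite, against 6.2), and 7 other splits of the pools gave 55 to 395 genes where the real one gave 750. In every class and comparison the count without the filter was larger, between 38 and 716. Among the genes that passed only with the block were Isg15 (0.92, adjusted p 0.0526 without and 0.0158 with it), Plac8 (0.99, 0.0991 and 0.0277), Smoc1 (−0.82, 0.0856 and 0.0320) and the integrin Itga8 (−0.94, 0.0685 and 0.00142), which is also a marker of SMC. Cilp passed without any 1 of the 8 pools. Dkk2 had an adjusted p of 0.0521 without control pool 1 of 8 weeks, and Ifit1 of 0.0598 without control pool 2 of 4 weeks. Hspa1a lost its call without control pool 1 of 8 weeks (0.0587), ImP pool 1 (0.0882) or 2 (0.0529) of 4 weeks, or ImP pool 1 of 8 weeks (0.0804). The other 9 genes lost theirs in 5 to 7 of the 8 fits that left out 1 pool, with adjusted p values up to 0.169 (Hyou1 and Trp53inp1). The count was 3 without control pool 2 of 4 weeks, 7 without control pool 1 of 4 weeks, 7 without control pool 1 of 8 weeks and 6 without ImP pool 1 of 4 weeks. It was 6 without ImP pool 1 of 8 weeks, 24 without ImP pool 2 of 8 weeks and 59 without control pool 2 of 8 weeks. Cluster 2 holds most fibroblasts of control pools and cluster 1 most of those of ImP pools. Within cluster 2 alone 4 genes passed, all higher with ImP: Cilp (0.90, adjusted p 0.0342), Hyou1 (0.79, 0.0342), the ER stress gene Manf (0.70, 0.0465) and the matrix gene Sparcl1 (0.64, 0.0342). Within cluster 1 alone none passed by edgeR, where 748 had an unadjusted p under 0.05, and DESeq2 was not run on the clusters. The replicate block gave 36 genes in cluster 1 (6 higher, 30 lower) and 12 in cluster 2 (9 higher, 3 lower).

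**Figure D2:**
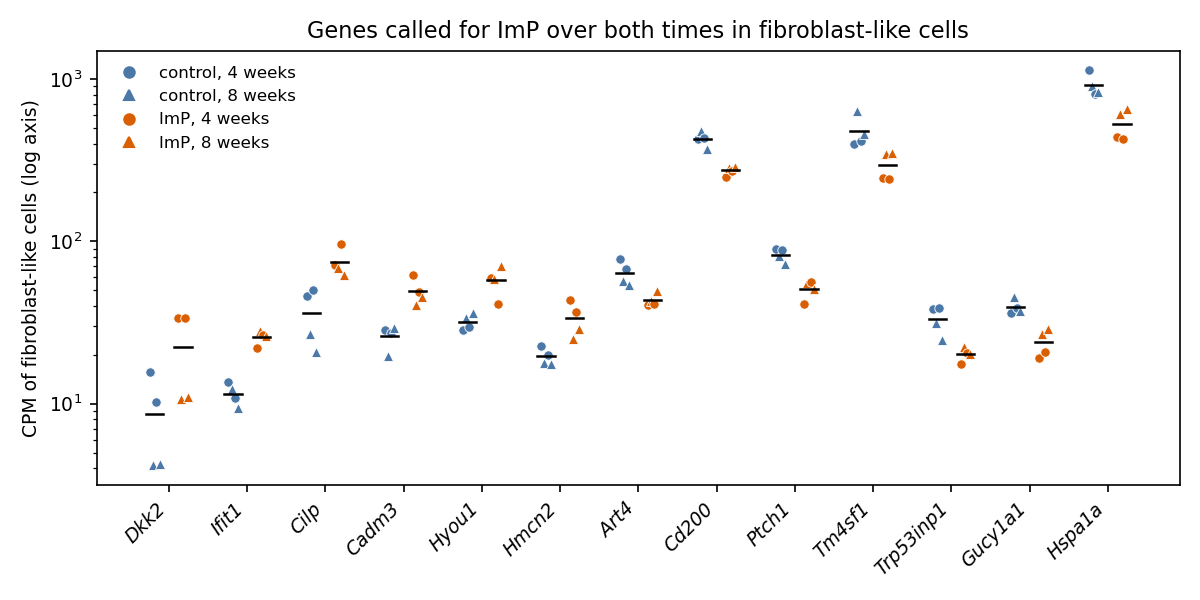
Level of the 13 genes that passed for ImP over both times in fibroblasts, as CPM per pool on a log axis, with control pools in blue, ImP pools in orange, circles for 4 weeks and triangles for 8 weeks. Black bars are means of 4 pools; Ifit1 averaged 25.6 CPM with ImP and 11.5 CPM in controls.

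Genes induced by type I interferon were higher in the fibroblasts of ImP pools, as were genes of the ER stress response. Of 16 tested interferon genes 15 had a positive fold change, and the median of the list was 0.52 (camera adjusted p 2.27e-16; adjusted p 0.399 with an estimated correlation). Adjusted over the list alone 10 members rose, among them Ifit1, Isg15 (0.92), Ifi27l2a (0.85) and Oasl2 (0.71), and over all genes only Ifit1. All 16 ER stress genes had a positive fold change, with a median of 0.39 (adjusted p 4.96e-12; adjusted p 0.477 with an estimated correlation), and 8 rose adjusted over the list alone but none over all genes. These included the chaperone Hspa5 (0.47), Manf (0.66), Sdf2l1 (0.66) and the transcription factor Xbp1 (0.41). The interferon list was higher with ImP by 0.45 in run 1 and 0.60 in run 2, and the ER stress list by 0.34 and 0.36 (mean of log2 values). Over the 4 pools of each arm, the interferon level had an exact permutation p of 0.0286 and the ER stress level of 0.0571. The adjusted p values over 77 lists were 0.440 and 0.550. With a lowest p of 0.0286, this test could pass after adjustment only if most of the lists lay at that p. Within the clusters over both times, the interferon list was called in cluster 1 (median 0.40, adjusted p 4.28e-12) but not in cluster 2 (0.07, adjusted p 0.298), where it fell at 4 weeks (−0.24, adjusted p 0.0360) and rose at 8 weeks (0.35, adjusted p 6.16e-06). The ER stress list was called in each (0.35 in both).

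Genes of fibroblast progenitors of the outer wall rose in the fibroblasts, and contractile genes fell. All 11 progenitor genes had a positive fold change (median 0.37, adjusted p 2.86e-07; adjusted p 0.477 with an estimated correlation), and adjusted over the list alone 4 rose, among them Ly6c1 (0.50), Sema3c (0.49) and Ly6a (0.37). Ly6c1 is also one of the genes that mark cluster 1, and the list was not called within either cluster. All 15 contractile genes of SMC had a negative fold change (median −0.79, adjusted p 1.17e-12; adjusted p 0.477 with an estimated correlation), and adjusted over the list alone 8 fell, among them Cnn1 (−1.39), Acta2 (−1.09), Des (−0.90) and Mylk (−0.70), though none did over all genes. Fibroblasts are not the main source of these genes in the wall, and without the 125 fibroblasts (2.82%) that held other SMC-specific transcripts the median was −0.11 (adjusted p 0.0509). The TGF-beta response list fell (median −0.22, adjusted p 0.00525; adjusted p 0.399 with an estimated correlation) with Ltbp2 (−0.71) and Tgfb3 (−0.37) lower and Fn1 (0.60) higher adjusted over the list alone, and its adjusted p was 0.0532 without ImP pool 2 of 4 weeks. It was not called within cluster 1 (−0.12, adjusted p 0.278) or cluster 2 (−0.05, adjusted p 0.315).

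The collagen gene Col1a1 (−0.11, adjusted p 0.775), the adhesion molecules Vcam1 (−0.54, 0.379) and Icam1 (−0.22, 0.365), the chemokine Ccl2 (0.26, 0.917) and Acta2 (−1.09, 0.272) did not pass in fibroblasts by edgeR. Neither did Nisch, the gene of the imidazoline receptor to which ImP is thought to bind, with 143 ± 10.7 CPM with ImP and 129 ± 10.4 CPM in controls (SD, n = 4 each; log2 fold change 0.14, adjusted p 0.489), nor Apoe (0.02, 0.982).

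In SMC no gene passed for ImP over both times by edgeR, although 651 had an unadjusted p under 0.05 and DESeq2 called 10. Rasl11b, a small GTPase, was among the genes with the smallest p values (104 ± 4.94 CPM with ImP, 134 ± 8.36 in controls, SD, n = 4 each; log2 fold change −0.36, adjusted p 0.299 by edgeR). By the fit with a replicate block 5 genes passed, among them Rasl11b (adjusted p 0.0447) and Sost (−0.26, 0.0329). Vcam1 (0.85, adjusted p 0.815), Acta2 (−0.13, 0.968), Col1a1 (−0.02) and Nisch (0.03; 121 ± 9.83 against 119 ± 2.78 CPM) were not called, nor were Icam1 (0.39) and Apoe (0.38), both near 1 CPM or lower.

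The genes that SMC switch on when they leave the contractile state were higher in the SMC of ImP pools. Of 14 tested members 12 had a positive fold change (median 0.33, adjusted p 4.85e-07; adjusted p 0.328 with an estimated correlation). Adjusted over the list alone Tnfrsf11b (0.62) and Timp1 (0.88) rose, and over all genes none did. The list level was higher by 0.38 in run 1 and 0.24 in run 2 (exact permutation p 0.0571, adjusted p 0.550 over 77 lists). The contractile list was not called in SMC over both times (difference in level −0.048, exact permutation p 0.371). Per pool the level of the modulation list was 6.636 to 7.296 in fibroblasts and 3.839 to 4.499 in SMC. Fibroblasts were a larger part of the cells of ImP pools, and their RNA was not tested for as a source of this rise. The ER stress list also rose in SMC (13 of 16 members positive, median 0.10, adjusted p 3.90e-05; adjusted p 0.477 with an estimated correlation), with 5 members higher adjusted over the list alone, as Manf (0.35) and Xbp1 (0.34). The matrix remodelling list, with proteases and their inhibitors, rose with a median of 0.03 and a mean of 0.17 (adjusted p 0.0115; adjusted p 0.413 with an estimated correlation), and Mmp3 (0.99) and Timp1 were higher adjusted over the list alone. Mmp3 also marks fibroblast cluster 2, with 575 to 1096 CPM in the fibroblasts of each pool and 2.89 to 11.99 CPM in SMC, and RNA from fibroblasts was not tested for in SMC. These 3 lists were called without any 1 of the 8 pools.

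In macrophages no gene passed over both times by edgeR, with 265 at an unadjusted p under 0.05 and 1 called by DESeq2. Without control pool 2 of 8 weeks 2 passed, and without ImP pool 1 of 8 weeks 1. The gene called by DESeq2 was Cd209d, a lectin of resident macrophages, with 163 ± 66.1 CPM with ImP and 56.8 ± 31.0 in controls (SD, n = 4 each; log2 fold change 1.60, SE 0.266, adjusted p 0.343, 0.0283 with a replicate block). Next came the interferon gene Ifit3 (1.93, adjusted p 0.988). Col1a1 (−1.55, 0.988), Vcam1 (−0.83, 0.988), Apoe (0.35, 0.988), Ccl2 (0.22), Acta2 (0.08), Icam1 (−0.06) and Nisch (0.03) were not called. The heat shock list fell (9 of 10 members lower, median −0.34, adjusted p 3.29e-07; adjusted p 0.477 with an estimated correlation), with Hspe1 (−0.70) and Hsph1 (−0.66) lower adjusted over the list alone. A list of progenitor genes that are not typical of macrophages fell as well (6 members, median −1.07, adjusted p 4.57e-04; adjusted p 0.399 with an estimated correlation), with Ly6a (−1.72) lower adjusted over the list alone. The 5 tested cell cycle genes had a median of −0.67 (adjusted p 1.91e-04; adjusted p 0.399 with an estimated correlation), which was no longer called without control pool 2 of 8 weeks (adjusted p 0.107). The macrophage sums were the smallest, from 342533 UMIs, and on simulated data only 15.2% of 1.5-fold changes were found in them, against 52.2% in fibroblasts and 71.6% in SMC.

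Across the 3 classes 26 of 77 list tests passed over both times, 13 higher and 13 lower, and 9 of these held without any 1 pool. With an estimated correlation none passed, with adjusted p values of 0.328 to 0.731 for the called lists. With a replicate block 29 passed: 4 more (in fibroblasts the MHC class II list, adjusted p 0.0121, and the ribosomal list, 0.0108; in macrophages the MHC class II list, 0.00244; in SMC the mitochondrially encoded list, 0.0442), while the cholesterol synthesis list in macrophages was lost (0.0422 without, 0.0710 with). Lists that passed but lost their call without at least 1 pool were, in SMC, cholesterol synthesis (median 0.09, adjusted p 0.00257), complement (0.13, 0.0211) and heat shock (−0.03, 8.79e-04). In fibroblasts they were complement (0.23, 0.0211), leukocyte adhesion (−0.24, 0.0166), mitochondrially encoded (−0.13, 0.0123) and TGF-beta response genes. In macrophages interferon (0.28, 5.97e-04), lipid-laden (0.17, 0.0456), resident macrophage (0.11, 0.0199) and ER stress genes (0.15, 0.0417) rose. Collagen (−0.74, 4.34e-04), MHC class I (−0.24, 0.0199), oxidative phosphorylation (−0.13, 0.0021) and ribosomal protein genes (−0.20, 7.19e-05) fell. No class passed without the block for hypoxia (adjusted p 0.592 to 0.610), glycolysis (0.136 to 0.841), oxidative stress (0.269 to 0.948), immediate early (0.0728 to 0.736), NF-kB and inflammation (0.0796 to 0.594), mTORC1 target (0.269 to 0.347) or MHC class II genes (0.136 to 0.862). Within single fibroblast clusters some of these lists were called, and others that the whole class did not call. In cluster 2 immediate early (15 of 16 positive, median 0.21, adjusted p 2.42e-09), NF-kB (0.17, 0.0113), mTORC1 target (0.16, 5.49e-04) and cholesterol synthesis genes (0.23, 1.27e-04) were higher. In cluster 1 glycolysis (−0.13, adjusted p 7.75e-04), oxidative phosphorylation (−0.15, 1.13e-04) and heat shock genes (−0.08, 0.0132) were lower. An estimated correlation was not tried within clusters.

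**Figure D3:**
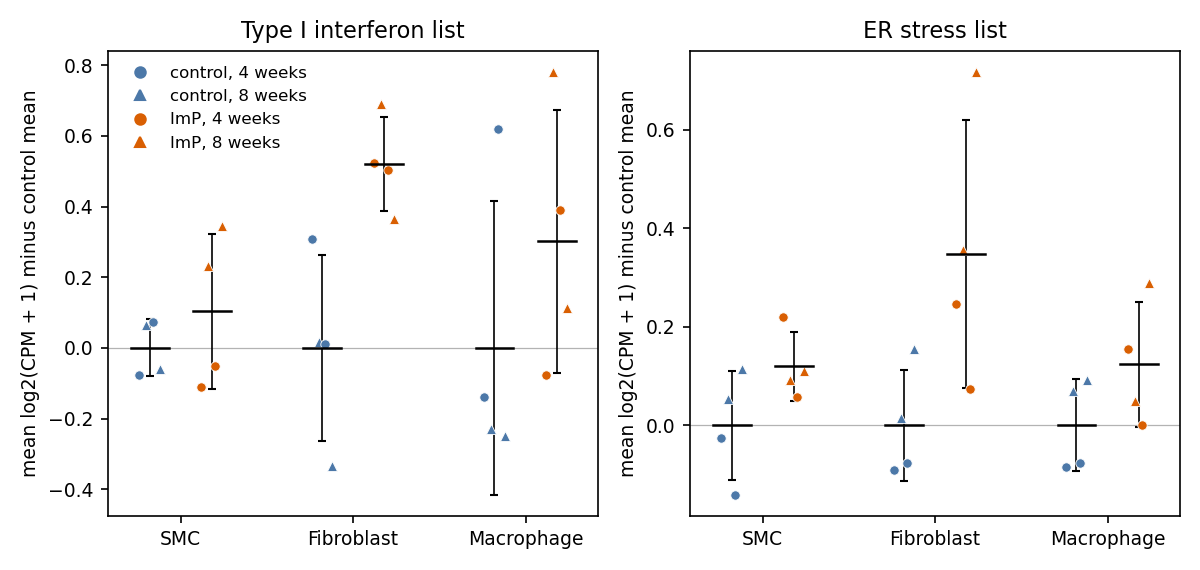
Level of the type I interferon and ER stress lists (mean log2(CPM + 1) of the members minus the control mean) per pool in SMC, fibroblasts and macrophages, with control pools in blue, ImP pools in orange, circles for 4 weeks and triangles for 8 weeks. Black bars are means of 4 pools with SD; in fibroblasts the interferon list differed by 0.52 between arms, without overlap.

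At 4 weeks of ImP the smallest p values in fibroblasts belonged to Hspa1a and Dkk2, neither of which passed. Hspa1a averaged 431 CPM with ImP and 967 CPM in controls (log2 fold change −1.16, SE 0.145, adjusted p 0.0570), and Dkk2 33.5 and 12.96 CPM (1.40, SE 0.178, adjusted p 0.0570), in 2 pools each. By edgeR 0 genes passed in fibroblasts, with 1045 at an unadjusted p under 0.05 and 57 called by DESeq2. With a replicate block 44 passed (8 higher, 36 lower), among them Hspa1a (0.00907), Dkk2 (0.0157), Cadm3 (0.99, 0.0365), Hmcn2 (0.91, 0.0256) and Itga8 (−1.19, 0.00459). Without the fibroblasts that held SMC-specific transcripts, 10 genes passed. Leaving out control pool 1 of 8 weeks gave 23 genes and control pool 2 of 8 weeks 22. Leaving out control pool 1 or control pool 2 of 4 weeks gave 2 genes each, and ImP pool 1 of 4 weeks 1. Nisch (0.16), Vcam1 (−0.71), Icam1 (−0.32), Ccl2 (−0.71), Col1a1 (−0.19), Acta2 (−1.09) and Apoe (−0.32) were not called, with adjusted p values of 0.506 or more.

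In the SMC of 4 weeks, genes of cholesterol synthesis and of ER stress were higher with ImP. The cholesterol list rose with 15 of 19 members positive (median 0.21, adjusted p 1.18e-07; adjusted p 0.412 with an estimated correlation), and Fdps (0.53), Idi1 (0.52), Sqle (0.52) and Msmo1 (0.43) passed adjusted over the list alone. The ER stress list rose with 15 of 16 members positive (median 0.24, adjusted p 1.01e-07; adjusted p 0.412 with an estimated correlation), and 5 members passed adjusted over the list alone, as Sdf2l1 (0.81), Manf (0.46) and Hspa5 (0.35). No gene passed over all genes in SMC by edgeR, with 611 at an unadjusted p under 0.05 and 3 called by DESeq2. Without control pool 1 of 4 weeks 2 passed. The chaperone pair Hspa1a and Hspa1b had the smallest p (−0.75 each, adjusted p 0.226). By the fit with a replicate block 8 passed, among them both (0.0256), Gja1, a gap junction gene (0.53, 0.0256), Inhba (0.39, 0.0256), Tnfrsf12a (0.46, 0.0383) and Pecam1 (−0.59, 0.0306). Vcam1 (0.32), Icam1 (−0.36), Acta2 (0.04), Col1a1 (0.02), Nisch (0.07) and Apoe (−0.02) were not called.

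The fibroblast lists at 4 weeks included interferon genes (14 of 16 positive, median 0.26, adjusted p 6.07e-06; adjusted p 0.526 with an estimated correlation), ER stress genes (median 0.24, adjusted p 5.40e-05; adjusted p 0.612 with an estimated correlation) and progenitor genes (11 of 11 positive, median 0.49, adjusted p 5.71e-09; adjusted p 0.412 with an estimated correlation), all higher. Within cluster 2 alone, however, the interferon list fell (median −0.24, adjusted p 0.0360), while it rose in cluster 1 (0.17, adjusted p 0.00495). The progenitor list was not called in cluster 1 (adjusted p 0.101) or cluster 2 (0.141). Has1, which makes hyaluronan (1.62), and Ly6c1 (0.68) rose adjusted over the progenitor list alone. Contractile genes fell (median −0.94, adjusted p 5.71e-09; adjusted p 0.526 with an estimated correlation), and without the cells that held SMC-specific transcripts their median was −0.18 (adjusted p 0.0343). In macrophages the 5 cell cycle genes fell (median −1.87, adjusted p 2.64e-08; adjusted p 0.412 with an estimated correlation), and Top2a (−3.05), Mcm5 (−2.29) and Mki67 (−1.87) were lower adjusted over the list alone. All 16 immediate early genes had a positive fold change in macrophages (median 0.25, adjusted p 6.07e-06; adjusted p 0.412 with an estimated correlation). MHC class II genes, which present antigen, fell (median −0.78, adjusted p 1.39e-04; adjusted p 0.434 with an estimated correlation), and this call was lost without control pool 1 of 4 weeks (adjusted p 0.357).

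No gene passed in macrophages at 4 weeks by edgeR, with 284 at an unadjusted p under 0.05, 1 called by DESeq2 and 5 with a replicate block, and 1 passed without control pool 1 of 8 weeks. The neutrophil chemokine Cxcl2 averaged 1586 CPM with ImP and 606 CPM in controls (log2 fold change 1.39, SE 0.228, adjusted p 0.309, 0.00338 with the block), and Top2a (−3.05, adjusted p 0.985, 0.0277 with the block) and H2-Q7 (−2.15, 0.985, 0.0468 with the block) were lower. Col1a1 (−1.80), Vcam1 (−0.69), Apoe (0.21), Acta2 (0.21), Nisch (0.24), Icam1 (0.16) and Ccl2 (−0.12) were not called. Over the 3 classes 29 of 77 lists passed at 4 weeks (15 higher, 14 lower; 33 with a replicate block), 8 of them without any 1 pool, and the lowest adjusted p with an estimated correlation was 0.412. The 4 lists called only with the block were contractile genes in SMC (median 0.05, adjusted p 0.0117), MHC class II and MHC class I in fibroblasts (0.0396 each) and ER stress in macrophages (0.0396).

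At 8 weeks of ImP, interferon genes were higher than in controls of 8 weeks in SMC, fibroblasts and macrophages, though to different degrees. In fibroblasts all 16 members had a positive fold change (median 0.74, adjusted p 1.48e-19; adjusted p 0.330 with an estimated correlation), and 10 rose adjusted over the list alone, as Ifit1 (1.32) and Isg15 (1.13). In macrophages 15 of 16 were positive (median 0.80, adjusted p 1.06e-14; adjusted p 0.330 with an estimated correlation), and 6 rose adjusted over the list alone, as Ifit3 (2.27) and Irf7 (1.46). In SMC all 14 were positive (median 0.27, adjusted p 8.58e-05; adjusted p 0.330 with an estimated correlation), with none called adjusted over the list alone. Each of these 3 calls held without any 1 pool. In fibroblasts the list level of ImP pools 1 and 2 was 4.815 and 4.795 at 4 weeks and 4.982 and 4.656 at 8 weeks. In control pools 1 and 2 it was 4.598 and 4.301 at 4 weeks and 4.307 and 3.957 at 8 weeks. The larger difference at 8 weeks was thus not in the ImP pools alone.

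SMC of ImP pools at 8 weeks had lower contractile and higher modulation genes than SMC of controls of 8 weeks. The contractile list fell with 15 of 16 members negative (median −0.14, adjusted p 1.31e-04; adjusted p 0.330 with an estimated correlation), none of them called adjusted over the list alone. Its level in ImP pools 1 and 2 of 8 weeks (9.39 and 9.424) was below that in controls of 8 weeks (9.543 and 9.561). It lay between the levels of the controls of 4 weeks (9.349 and 9.445). The modulation list rose with 11 of 14 positive (median 0.30, adjusted p 1.95e-06; adjusted p 0.330 with an estimated correlation), and adjusted over the list alone 5 rose, among them Timp1 (1.42), Vcam1 (1.37), Lum (0.85) and Tnfrsf11b (0.67). Lum is abundant in fibroblasts, with 886 to 1154 CPM per pool against 4.22 to 9.81 CPM in SMC. RNA from fibroblasts was not tested for as a source of the rise of this list. By edgeR 1 gene passed in SMC, with 634 at an unadjusted p under 0.05, 4 called by DESeq2 and 40 with a replicate block (20 each way). It was Dbp, a transcription factor of the circadian clock, with 14.6 ± 4.54 CPM with ImP and 8.74 ± 1.88 in controls over both weeks (SD, n = 4 each; log2 fold change at 8 weeks 1.31, SE 0.164, adjusted p 0.0337, 0.00479 with the block). It was below 20 CPM and was named after its values had been seen, and it lost its call without control pool 1 (0.179), control pool 2 (0.0516), ImP pool 1 (0.108) or ImP pool 2 (0.0672) of 8 weeks. The count was 3 without control pool 1 of 4 weeks, control pool 2 of 4 weeks or ImP pool 2 of 8 weeks, and 4 without ImP pool 1 of 4 weeks. Genes that passed with the block only included Tef (0.63, 0.0292), Nfil3 (−0.65, 0.0336), Gm12840 (−0.49, adjusted p 0.202 without and 0.0292 with it), Txnip (0.48, 0.0377), Foxs1 (0.54, 0.0377) and Irs2 (−0.66, 0.0377). Acta2 (−0.30), Icam1 (1.15), Apoe (0.78), Col1a1 (−0.06) and Nisch (−0.02) were not called, and Vcam1 was not called over all genes (adjusted p 0.604).

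Fibroblasts at 8 weeks had a higher ER stress response and more Cilp, though no gene passed. The ER stress list rose with 15 of 16 members positive (median 0.52, adjusted p 2.03e-13; adjusted p 0.390 with an estimated correlation), and 8 rose adjusted over the list alone, as Herpud1 (0.92), Dnajb9 (0.79) and Manf (0.72). Complement genes rose (median 0.11, adjusted p 0.00304; adjusted p 0.363 with an estimated correlation) with C4b (0.78) and C3 (0.64), a call that was lost without control pool 1 of 8 weeks (adjusted p 0.220). C3 is also one of the genes that mark cluster 1. Contractile genes fell (median −0.73, adjusted p 2.53e-08; adjusted p 0.554 with an estimated correlation), which was lost without control pool 2 of 8 weeks (adjusted p 0.395). Without the cells that held SMC-specific transcripts the median was −0.07 and not called (adjusted p 0.295). By edgeR 0 genes passed, with 824 at an unadjusted p under 0.05, 17 called by DESeq2 and 7 with a replicate block. Cilp averaged 65.6 CPM with ImP and 24.0 CPM in controls (log2 fold change 1.46, SE 0.171, adjusted p 0.0752, 0.0152 with the block), and Dnajb9 had an adjusted p of 0.371 (0.0612 with the block). Others that passed with the block were Gpx3, an antioxidant enzyme that also marks cluster 1 (1.02, 0.0115) and Sost, which also marks SMC (−1.24, 0.0333). Cx3cr1, a gene of myeloid cells, passed there too (−1.92, 0.0152). Leaving out 1 pool gave 2 genes without control pool 1 of 8 weeks. It gave 1 gene without control pool 2 of 8 weeks, without either control pool of 4 weeks or without either ImP pool of 4 weeks. Ccl2 (1.23), Acta2 (−1.10), Vcam1 (−0.36), Apoe (0.36), Icam1 (−0.13), Nisch (0.13) and Col1a1 (−0.03) were not called.

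In macrophages at 8 weeks no gene passed by edgeR, with 181 at an unadjusted p under 0.05, 1 called by DESeq2 and 3 with a replicate block. Without control pool 2 of 8 weeks 13 passed, and without control pool 1 of 8 weeks 2. Cxcl2 averaged 724 CPM with ImP and 1774 CPM in controls (log2 fold change −1.29, adjusted p 0.519, 0.00657 with the block), and Il1b, an inflammatory cytokine, passed with the block only (−1.92, 0.0232), as did Hist1h1b (2.62, 0.0498). Rasgef1b had the next smallest p (−2.18, adjusted p 1.00, 0.0882 with the block). Col1a1 (−1.29), Vcam1 (−0.98), Ccl2 (0.56), Apoe (0.48), Icam1 (−0.29), Nisch (−0.19) and Acta2 (−0.05) were not called. Over the 3 classes 24 of 77 lists passed at 8 weeks (12 higher, 12 lower), 6 of them without any 1 pool, and the lowest adjusted p with an estimated correlation was 0.330. With a replicate block 33 passed, adding in SMC matrix remodelling (0.0210), glycolysis (0.0437), mitochondrially encoded (0.00614), immediate early (0.0473) and complement genes (0.0463). In fibroblasts it added MHC class II (0.0278), glycolysis (0.0463), mitochondrially encoded (0.0250) and TGF-beta response genes (0.0191).

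The third question was whether the response to ImP differed between 8 and 4 weeks. In macrophages it did for Cxcl2, which was higher with ImP at 4 weeks and lower at 8 weeks. The difference between the log2 fold changes was −2.68 (SE 0.320, adjusted p 0.0120, 4.37e-05 with a replicate block). It was the only gene that passed in macrophages by edgeR, with 188 at an unadjusted p under 0.05. Cxcl2 kept its call without either control pool of 8 weeks and lost it without any of the other pools. Its adjusted p was 0.0900 without control pool 1 and 0.204 without control pool 2 of 4 weeks. It was 0.169 and 0.0749 without ImP pools 1 and 2 of 4 weeks, and 0.116 and 0.0516 without ImP pools 1 and 2 of 8 weeks. With doublet calls kept it was 0.0518 (−2.74). In fibroblasts, where Cxcl2 was at 1.42 to 11.29 CPM, the difference was −3.40 (SE 0.593; adjusted p 0.940 over all genes, 0.00338 over the NF-kB list alone). The control pools also differed between the times (606 CPM at 4 and 1774 CPM at 8 weeks), so the difference was not in the ImP pools alone. No gene passed in SMC (589 at an unadjusted p under 0.05, 2 called by DESeq2, 29 with the block) or fibroblasts (388, 1 called by DESeq2 and 0 with the block). In SMC 1 passed without control pool 2 of 8 weeks, and in fibroblasts 1 without control pool 1 of 8 weeks.

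Gene lists differed between the times in each class, 8 in SMC, 8 in fibroblasts and 8 in macrophages. In macrophages the response of interferon genes was higher at 8 than at 4 weeks (median difference 0.91, adjusted p 1.74e-09; adjusted p 0.462 with an estimated correlation), as was that of MHC class II genes (1.01, adjusted p 6.49e-07; adjusted p 0.471 with an estimated correlation) and cell cycle genes (1.91, adjusted p 2.45e-06; adjusted p 0.420 with an estimated correlation). For the last pair the medians were −0.78 and −1.87 at 4 weeks, and 0.10 and 0.04 at 8 weeks. NF-kB and inflammation genes (−0.53, adjusted p 2.34e-06; adjusted p 0.420 with an estimated correlation) and immediate early genes (−0.51, adjusted p 1.48e-07; adjusted p 0.420 with an estimated correlation) had a lower response at 8 weeks, having risen at 4 weeks (0.24 and 0.25) and fallen at 8 weeks (−0.29 and −0.13). The control pools moved between the times in all 5 lists, so these differences were not in the ImP pools alone. From 4 to 8 weeks the controls fell in interferon (−0.50, adjusted p 9.81e-06), MHC class II (−0.77, adjusted p 1.40e-06) and cell cycle genes (−1.39), and rose in NF-kB (0.34, adjusted p 3.40e-05) and immediate early genes (0.29). With an estimated correlation the adjusted p values of these 5 lists were 0.487, 0.461, 0.269, 0.394 and 0.366. The interferon (adjusted p 0.139) and NF-kB calls (0.353) were lost without control pool 2 of 4 weeks, and the MHC class II call without control pool 1 of 4 weeks (0.153) and 1 other pool. In SMC the difference was negative for the contractile list (−0.22, adjusted p 7.55e-05; median 0.05 at 4 and −0.14 at 8 weeks) and the cholesterol synthesis list (−0.29, adjusted p 2.32e-05; 0.21 and −0.03). The controls rose in both (0.15 and 0.23; adjusted p 0.366 each with an estimated correlation). The difference was positive for the interferon list (0.32, adjusted p 0.00123), with adjusted p values of 0.420, 0.471 and 0.462 with an estimated correlation. These 8 lists were called without any 1 pool, and of the 24 lists that passed in all (9 higher, 15 lower) the other 16 were not. With a replicate block 27 passed, adding 3 in fibroblasts: SMC modulation (0.0389), collagens and matrix (0.0490) and ER stress (0.0490).

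Controls at 8 weeks were compared with controls at 4 weeks to give the change with time and age alone. Collagen and matrix genes of the fibroblasts were lower in the older controls. All 20 members had a negative fold change (median −0.48, adjusted p 6.69e-24; adjusted p 0.269 with an estimated correlation), and adjusted over the list alone 14 fell, as Col3a1 (−0.92), Col1a1 (−0.80), Col15a1 (−0.68) and Eln, the gene of elastin (−0.58). In SMC the same list fell (median −0.17, adjusted p 1.40e-06; adjusted p 0.558 with an estimated correlation), while contractile genes (0.15, adjusted p 6.33e-05; adjusted p 0.366 with an estimated correlation), cholesterol synthesis genes (0.23, adjusted p 8.18e-08; adjusted p 0.366 with an estimated correlation) and ER stress genes (0.17, adjusted p 1.11e-05; adjusted p 0.461 with an estimated correlation) rose. In macrophages cell cycle genes fell (−1.39, adjusted p 8.39e-09; adjusted p 0.269 with an estimated correlation), with Top2a and Stmn1 (−1.39) lower adjusted over the list alone, and immediate early genes rose (0.29, adjusted p 1.55e-05; adjusted p 0.366 with an estimated correlation). Each of these calls held without any 1 pool.

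No gene passed between control times by edgeR. The counts at an unadjusted p under 0.05 were 622 in SMC, 703 in fibroblasts and 205 in macrophages, DESeq2 called 5, 16 and 1, and a replicate block gave 55, 14 and 4. Without control pool 2 of 8 weeks 6, 3 and 7 passed in these classes. Without control pool 1 of 4 weeks 1 passed in SMC, and in fibroblasts 3 did without control pool 2 of 4 weeks and 2 without control pool 1 of 8 weeks. The smallest p values in fibroblasts belonged to Prg4, which encodes lubricin (1.44, SE 0.201, adjusted p 0.111, 0.0273 with the block), and the basement membrane collagen Col4a5 (−0.76, SE 0.103, adjusted p 0.111, 0.00949 with the block), and within cluster 2 alone Prg4 passed (1.99, adjusted p 0.0182). In SMC they were Bcl6 (0.79, adjusted p 0.472, 0.0215 with the block) and Ccn3 (0.64, 0.472, 0.00205), and in macrophages Cxcl2 (1.54, 0.106, 8.00e-04) and Stmn1 (−1.39, adjusted p 1.00). Sparc (−0.59, 0.0220) in SMC and Il1b (2.34, 0.0085) and Top2a (adjusted p 0.0340, lower at 8 weeks) in macrophages passed with the block only. Over the 3 classes 28 of 77 lists passed (19 higher, 9 lower), 9 of them without any 1 pool. With the block 32 passed, adding MHC class II (0.0211), MHC class I (0.0137) and glycolysis genes (0.0303) in fibroblasts and ER stress genes in macrophages (0.0351). No share of cells passed between control times by edgeR, as macrophages with 3.91% ± 1.47 at 4 weeks and 11.3% ± 9.95 at 8 weeks (SD, n = 2 each; log2 fold change 1.54, adjusted p 0.505).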

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

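All tests of explanations in this part were chosen after the result was seen, except the test of droplets shared by SMC and fibroblasts and the estimates of how much the fibroblast clusters' shares alone would move the interferon and ER stress lists. The comparison within each cluster, for ER stress and for interferon at each week, and the interferon estimates per week were added after the outcome within clusters was known. The comparison of UMIs in the droplet test was added after the medians had been seen.

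Pools of an arm were compared over both weeks, since each group had only 2, and 11 of 118 such sets of 4 pools had 1 pool far from the other three, where chance gives about 1 in 20. ImP pool 1 of 8 weeks stood apart in its share of B cells (gap 0.976 of the range; 11.3%, 95% exact interval 9.89 to 12.8, against 0.071% to 0.34%). It also stood apart in T cells (0.967; 4.67%, interval 3.76 to 5.74, against 0.136% to 0.284%) and macrophages (0.85; 9.02%, interval 7.75 to 10.4). Control pool 2 of 8 weeks stood apart in fibroblasts (0.977; 23.4%, interval 21.3 to 25.6), fibroblast cluster 2 (0.8295; 12.1%, interval 10.5 to 13.8) and macrophages (0.866; 18.4%, interval 16.5 to 20.4). The intervals cover counting error only. Acta2 in fibroblasts was high in ImP pool 2 of 8 weeks (0.849; 613 CPM), and Cd209d in macrophages in control pool 2 of 4 weeks (0.845; 103 CPM). Rasgef1b in macrophages was high in control pool 1 of 8 weeks (0.838; 134 CPM), Stmn1 in macrophages in ImP pool 1 of 4 weeks (0.89; 139 CPM), and Vcam1 in SMC in control pool 1 of 8 weeks (0.848; 12.2 CPM).

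The response to ImP differed between 8 and 4 weeks by a test of the difference for Cxcl2 in macrophages (−2.68, adjusted p 0.0120 by edgeR). In SMC the lists that differed, with the median difference, were contractile (−0.22), interferon (0.32), MHC class I (0.34), mTORC1 targets (−0.14), cholesterol synthesis (−0.29), ER stress (−0.32), immediate early (−0.34) and TGF-beta response (−0.14). In fibroblasts they were NF-kB and inflammation (−0.07), interferon (0.32), MHC class I (0.19), oxidative phosphorylation (−0.10), ribosomal proteins (−0.13), immediate early (−0.23), heat shock (0.21) and adventitial progenitor (−0.28). In macrophages they were NF-kB and inflammation (−0.53), interferon (0.91), MHC class II (1.01), MHC class I (0.68), mTORC1 targets (−0.20), cholesterol synthesis (−0.55), immediate early (−0.51) and cell cycle (1.91). None passed with an estimated correlation, and 16 of the 24 lists lost their call without at least 1 pool.

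SMC made up less and fibroblast cluster 1 more of the cells of ImP pools. A loss of SMC alone would leave the ratio of cluster 1 to cluster 2 as it was. The log2 of this ratio was higher with ImP by 0.95 (exact permutation p 0.0286). It comes from the same shares in which the pattern was seen, so it describes them and is no separate test. In run 2 at 8 weeks both clusters were higher with ImP (cluster 1 24.2% against 11.3%, cluster 2 25.4% against 12.1%). There the ratio does not argue against a loss of SMC alone. Macrophages, whose share such a loss would raise, made up 18.4% of that control pool and 4.82% of that ImP pool. This pair cannot decide the question, since it is 1 pool per arm and its control pool stood apart in macrophages and fibroblasts. Cells with few UMIs are argued against as the whole cause, since among cells with at least 5000 UMIs the SMC share still fell (−0.573, adjusted p 0.0423). More outer wall left on the ImP aortas cannot be told apart from a change in the wall: macrophages per 100 cluster 1 cells differed by −40.7 between arms (exact permutation p 0.286), with control pools up to 163. An effect of ImP on the wall stays open as well.

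Contractile genes were lower in the fibroblasts of ImP pools. Free RNA from SMC would lower them in macrophages too, where the median was 0.06 (adjusted p 0.841). The difference went from −0.64 to −0.09 (exact permutation p 0.571) when the 125 cells with other SMC-specific transcripts were left out, as droplets shared by an SMC and a fibroblast would give. But these cells had a median of 1.09 times the UMIs of the fibroblasts of their pool (95% bootstrap interval 0.97 to 1.22), and the 102 called doublets 1.66 times. The 40 of them with at least 1.5 times held 61.3% of their contractile UMIs. Shared droplets thus cannot be told apart from single cells that hold both sets of transcripts, which the test also leaves out. These cells were 4.40% ± 2.65 of fibroblasts in controls and 1.57% ± 1.11 with ImP (SD, n = 4 each; exact permutation p 0.0857), and they held 49.1% of the contractile UMIs. Chance cannot be excluded either, since the score of the list was 7.758 and 7 of 34 splits of the pools, fitted with the week as a term, gave as large a value, up to 11.272.

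Interferon and ER stress genes were higher in the fibroblasts of ImP pools. No single pool carried either list. When 1 pool was left out, the adjusted p values were at most 1.001e-06 for interferon and 2.108e-06 for ER stress. For ER stress, a heat shock type of stress in digestion cannot be told apart from a response to ImP. Hspa1a fell (−0.81), but the heat shock list had a median of −0.03 (camera adjusted p 0.0577). Its level in fibroblasts was highest in ImP pool 2 of 8 weeks (9.191), as was that of ER stress (7.951). The heat shock level was 8.317 to 8.516 in the other ImP pools and 8.508 to 8.903 in controls. A stress in digestion with immediate early genes cannot be told apart from a response to ImP, since that list rose within cluster 2 (0.214, adjusted p 2.42e-09) but was not called within cluster 1 (−0.02, adjusted p 0.713), while ER stress was called in both. The cluster shares alone would move ER stress by −0.02 against an observed 0.39, and the list was called within cluster 1 and cluster 2, though the remainder overlapped between arms (exact permutation p 0.0571). For interferon over both times they would move it by 0.114 against 0.48, and it was called within cluster 1 but not cluster 2 (adjusted p 0.298), so a part from the clusters cannot be told apart from a response to ImP. At 8 weeks they would move it by 0.072 against 0.69 and it rose within cluster 1 (0.68, adjusted p 2.71e-12) and cluster 2 (0.35, adjusted p 6.16e-06), which argues against the clusters as the whole cause. At 4 weeks they would move it by 0.156 against 0.26 while it fell within cluster 2 (−0.24, adjusted p 0.0360), so there the cluster shares may explain most of it. Of 34 splits 1, the real one, reached the interferon score of 8.583 (highest other 7.975), which is the smallest share that these splits can give. The list was put to this test after its score had been seen, and the splits took no account of the run. Chance is thus not excluded by this score. The exact permutation test of the list level (adjusted p 0.440 over 77 lists) cannot decide this either. Its lowest p is 0.0286, so it could pass only if most of the lists lay at that p. For ER stress 2 splits reached the score of 7.333 (highest other 7.785), so chance cannot be excluded.

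The same 34 splits, fitted with the week as a term, were used for the counts of genes. In SMC the real split gave 0 genes and the highest other 677, and in macrophages 0 and 93. All 34 of 34 splits reach a count of 0 whatever the data, so for these classes the count tests nothing. In fibroblasts 2 of 34 splits gave as many as the real 15, so by this count chance cannot be excluded, although the other was the split of run 1 from run 2, with 51, which is a known batch. In each class the highest was this split by run, which points to a difference between runs, and without it the highest others were 2, 6 and 39 in SMC, fibroblasts and macrophages. With the run as a replicate block the real split gave 183 genes in fibroblasts and the highest other 2, and 1 of 8 splits that part every pair of a run reached 183, but 8 are too few for a share under 0.05. In SMC the blocked real split gave 0 and the highest other 32, with 8 of 8 at least 0, and in macrophages 2 splits gave 2, the real one and another. For called lists chance cannot be excluded: in SMC 26 splits gave at least the real 6 (highest other 13), in fibroblasts 18 at least 9 (highest 12) and in macrophages 2 at least 13 (highest 13).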

How the results depend on the processing

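Settings chosen after the data had been seen were cells with at least 5000 UMIs, totals without lymphocytes or also without macrophages, each fibroblast cluster alone, and fibroblasts without cells holding SMC-specific transcripts. No called fold change changed sign, but uncalled ones did, as the share of B cells and of lymphatic ECs. Of the values of single fold changes, 2250 kept direction and side of the threshold, 199 became called, 87 lost their call and 93 moved. Counts of genes stayed within 1.5 times in 148 cases and moved in 107, and counts of lists in 45 and 5. The cause of these changes was not tested. When a pool was left out, the other pool of its group was assumed to vary like the other groups.

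Counts of genes are given in the order 4 weeks, 8 weeks, both times, difference between times, and controls. With the replicate block they were 8, 40, 5, 29 and 55 in SMC, 44, 7, 192, 0 and 14 in fibroblasts and 5, 3, 1, 3 and 4 in macrophages. DESeq2 gave 3, 4, 10, 2 and 5 in SMC, 57, 17, 131, 1 and 16 in fibroblasts and 1 in each comparison in macrophages. Without a filter on low counts they were 73, 104, 102, 76 and 80, then 487, 238, 716, 74 and 154, then 55, 62, 52, 38 and 44, and 713 of the 716 genes also pass the filter. The prior degrees of freedom were then infinite, against 8.6, 6.2 and 8.5 with it, and in fibroblasts the 7 other splits that part every pair of a run gave 55 to 395 genes without it, against 750 for the real one. Equal cells per pool gave 1 and 0 in SMC at 4 and 8 weeks, and 2 and 1 in fibroblasts. Doublet calls kept gave 2 in SMC at 8 weeks, 1 over both times, and 0 for the difference in macrophages. Class by marker score gave 0 in SMC at 8 weeks and 1 over both times, 2 in fibroblasts at 4 weeks and 30 over both times (13 shared), and in macrophages 1 at 4 weeks and 2 in controls. Without cells holding SMC-specific transcripts fibroblasts gave 10 at 4 and 1 at 8 weeks. Cluster 2 alone gave 2 at 8 weeks, 4 over both times and 1 in controls, and cluster 1 alone 0 over both times. With an estimated correlation 0 lists passed in each comparison, against 29, 24, 26, 24 and 28.

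Log2 fold changes of shares became called in totals without lymphocytes and macrophages: for fibroblasts 0.661 at 4 weeks, 0.670 at 8 weeks and 0.665 over both, and for SMC −0.628, −0.541 and −0.584. In totals without lymphocytes fibroblasts had 0.681 over both times, and SMC −0.647 at 4 weeks and −0.562 over both. Among cells with at least 5000 UMIs they were 0.702 and −0.573 over both times, and lymphatic ECs moved to −0.208 at 8 weeks. By marker score lymphatic ECs moved to −0.581 at 8 weeks and T cells to −0.334 at 4 weeks.

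Leaving out each pool gave 0 to 2, 0 to 4, 0 to 0, 0 to 1 and 0 to 6 genes in SMC, 0 to 23, 0 to 2, 3 to 59, 0 to 1 and 0 to 3 in fibroblasts, and 0 to 1, 0 to 13, 0 to 2, 0 to 1 and 0 to 7 in macrophages. Lists ranged from 23 to 29, 17 to 33, 21 to 31, 17 to 28 and 28 to 40. Shares at 4 weeks, 8 weeks and both ranged from −1.881 to 3.527, −0.291 to 9.469 and −0.533 to 4.329 for B cells and from −5.797 to 1.60, −1.563 to 1.446 and −2.772 to 1.059 for lymphatic ECs. Macrophages ranged from −1.405 to 0.690 at 8 weeks and −0.523 to 0.525 over both, and T cells from −1.232 to 8.201 and −0.346 to 4.366. SMC stayed between −0.748 and −0.441 and fibroblasts between 0.379 and 0.884 at 8 weeks.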

Other observations

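The values of lymphocytes in this part were examined after their shares had been seen, and no test of an explanation was made of them.

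Most B and T cells came from ImP pool 1 of 8 weeks, with 208 of 230 B cells and 86 of 108 T cells. Its T cells often had UMIs of genes of naive and central memory T cells: Lef1 in 76.7%, Tcf7 in 73.3% and Ccr7 in 51.2%. The activation marker Cd44 was found in 16.3%. In SMC of the same pool the first 3 genes were found in 0.16% to 0.33% of cells, at a median of 16180 UMIs against 6242 in the T cells, and Cd44 in 22.02%. Its B cells had UMIs of Ighd in 88.9%, Fcer2a in 70.2% and Cr2 in 57.7%, genes of mature B cells that have not switched class. In SMC of that pool these were found in 0.16% to 0.49% of cells, and the B cells had a median of 5076.5 UMIs. The 22 T cells of the other pools had Lef1 in 40.9% and Cd44 in 54.5%. Control pool 2 of 8 weeks had 0 B cells of 1536, for which the limit of 3 cells gives a share of up to 0.195% and the 95% exact interval one of up to 0.24%.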
